A study of Zea mays with 24 samples.

How the data were processed

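RNA was measured by sequencing in roots and young shoots of maize (Zea mays) seedlings of 2 cultivars, named SS and ST in the labels. Seedlings at the 3-leaf stage received water or a salinity solution of 100 mM. There were 8 groups of 3 libraries, 24 libraries in all, and the series describes them as biological replicates sequenced as paired ends of 150 bp on an Illumina HiSeq instrument.

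The authors deposited 1 table of FPKM values per library (fragments per kilobase of feature, scaled to a library total), each with 50202 features. These deposited FPKM values are normalized to feature length and library total. TopHat2, Cufflinks and Cuffdiff are named, with no role or version, per the submitters' processing notes, which also name the genome build B73 RefGen v3. Of the features, 44146 carry identifiers with the prefix Zm00001d, which belongs to a later maize gene set than that build, so the annotation behind the values is uncertain and no coordinates are given. Another 3930 features carry a prefix that marks transcript models added to the reference set. The remaining features were 1798 ENSRNA, 174 GRMZM5G and 154 zma-MIR identifiers.

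The values were checked for the reads behind them. For each feature a length, and for each library a total, was sought that turned every value into a whole number of reads within 0.002 reads. This succeeded for 100% of the 40811 features with a value above 0. The values therefore behave as plain counts divided by length and total, and library totals were 19747198 to 28825226. The reads of the features made up at least 99.9993% of each total, so these totals hold reads assigned to features. Whether 1 count is a read or a fragment is not given in the sources used here; counts are called reads. On simulated data of 8000 features in 12 libraries, all 12 totals were recovered exactly. Recovered reads were used to state depth, to compare replicates and for an added test. A group of 3 libraries with 0 reads allows a level of up to 3 reads over the group's total depth. Such floors cover counting error only.

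Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with moderated variances that follow mean expression and Benjamini-Hochberg adjustment at an adjusted p of 0.05. A feature was tested when its FPKM was at least 1 in at least 3 libraries of the fit. Contrasts within a tissue came from 1 fit of its 12 libraries, and contrasts between tissues from 1 fit of all 24. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low features. In simulated libraries for salinity against water in SS roots, with 25984 features tested, 78.5% of the 1.5-fold, 92.5% of the 2-fold and 100% of the 4-fold changes were recovered, and 6.3% of the calls were false. For ST shoots, with 23519 features tested, 67.2%, 90.5% and 98.5% were recovered and 7.9% of the calls were false. For the difference between the cultivars' root responses, with 25973 features tested, the shares were 44.6%, 78.8% and 95.4%, with 3.4% false calls, and for the shoot responses, with 23513 tested, 58.5%, 79.7% and 96.9%, with 6.7% false calls. False calls were 2.5% for the cultivars in roots under water and 3.6% for the tissues in SS. Their share lay above the intended 5% in 3 of 6 simulations, on 148 to 189 calls each, too few to set these shares firmly apart from 5%. Few features were changed, in SS roots 65 by 1.5-fold, 67 by 2-fold and 64 by 4-fold, and group means were otherwise equal. The real contrasts called far larger shares, such as 38.7% in SS roots, so the simulated shares need not hold for them. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

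Names came from a reference gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. It matched 153 features, all miRNA genes, and 0 of the Zm00001d identifiers. The 43 gene lists fixed in advance therefore had 0 members, their tests could not be run, and a fixed panel of salt-response genes is not reported. Named genes were those with a reference name, an adjusted p under 0.05, a mean of at least 5 FPKM over the libraries compared and, outside interactions, groups that did not overlap. Up to 8 per direction were taken by size of change for salinity, 5 for interactions and cultivars and 3 for tissues. Features known by identifier only were limited to 2 per direction. The miRNA genes are precursor loci matched by identifier. Their recovered lengths reach 270 bases, against reads of 150 bp, and mature miRNAs were not measured. Genes discussed below were shorter than 1 read, such as zma-MIR1432 (89 bases), zma-MIR168a (104), zma-MIR164b (128) and zma-MIR408b (147). A full-length read cannot lie within such a feature, and which transcripts gave the reads is not known here.

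Alternatives chosen before the data were examined were a pseudocount of 0.1, a filter of any value above 0 or of FPKM of at least 5 in 3 libraries, median-of-ratios and quantile scaling, other sets of libraries in the fit, a replicate block, a fold floor of 2, an adjusted p of 0.01, a robust variance model, and leaving out each library. Limma's voom on recovered reads, counts at 2-fold or more under each alternative, tests by identifier class and the tissue-by-salinity contrast for 2 miRNA genes were added after the data were seen.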

Results

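Transcript levels (FPKM) were measured in roots and young shoots of the maize cultivars SS and ST after watering with water or a 100 mM salinity solution. Each of the 8 combinations of cultivar, tissue and treatment had 3 libraries. Library totals ran from 19747198 to 28825226 reads, so that a value of 0 in a group bounds a level but does not show absence. Within groups, log2 values of replicate libraries correlated across features with Pearson coefficients of 0.9953 to 0.9978. Replicate pairs had chi-square values per degree of freedom of 1.92 to 8.32, above the counting noise of independent counts. If both mates of a fragment were counted, that noise would be higher, and the lowest values may not exceed it. No library was treated as a duplicate.

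Cultivar was the main axis of variation within each tissue. In roots, cultivar accounted for 82.4% of the variance of log2(FPKM + 1), treatment for 8.4%, their interaction for 5.1% and differences within groups for 4.1%. In shoots the shares were 83.9%, 8%, 5% and 3.1%. Sequence or presence differences between each cultivar and the reference may add to the differences between cultivars here and below, and were not tested. The 100 most abundant features took 27.51% to 28.07% of reads in ST shoots and 19.35% to 22.69% in SS shoots, against 11.24% to 12.51% in roots.

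**Figure D1:**
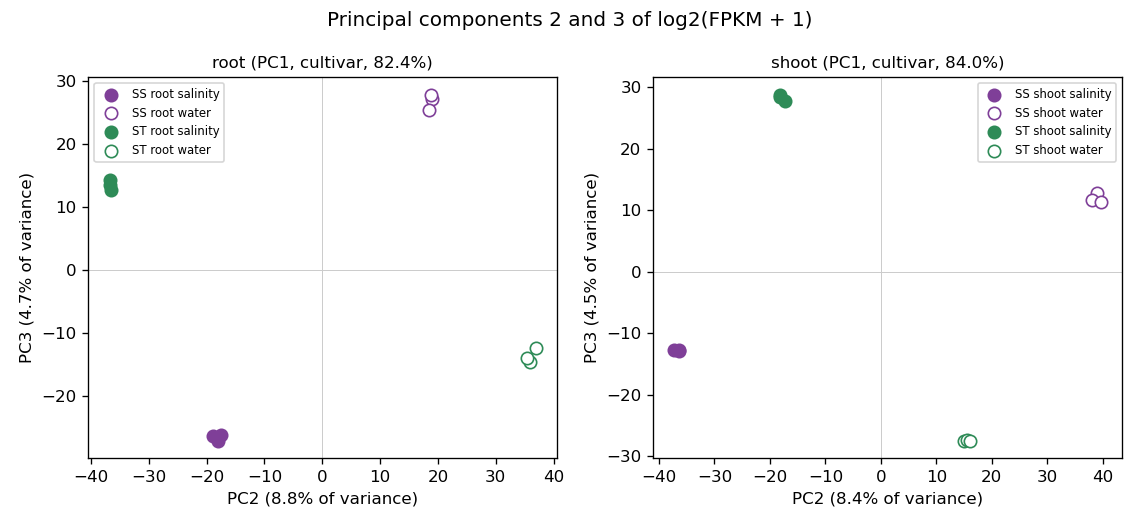
Scores of the 12 root and 12 shoot libraries on principal components 2 (x axis) and 3 (y axis) of log2(FPKM + 1); open circles are water, filled circles salinity, and each color is a cultivar. Component 2 separates the treatments in the same direction in both cultivars (8.8% of the variance in roots, 8.4% in shoots), and component 3 separates them in opposite directions (4.7% and 4.5%).

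The miRNA genes named here are precursor loci; how reads that match near-identical family members or antisense transcripts were assigned is not given in the sources used here, so values of single members such as zma-MIR168a and zma-MIR168b are uncertain in that respect.

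In SS roots, salinity lowered zma-MIR164b, a gene of the miRNA family that targets NAC transcription factor transcripts, and zma-MIR168a, of the family that targets ARGONAUTE1 transcripts. The level of zma-MIR164b fell from 31.5 ± 3.23 to 19.1 ± 2.17 FPKM (SD, n = 3 libraries each; log2 fold change -0.69, SE 0.09, limma adjusted p = 5.46e-05). That of zma-MIR168a fell from 102 ± 0.704 to 78.4 ± 7.54 FPKM (log2 fold change -0.39, limma adjusted p = 0.0137), a call lost without salinity replicate 3 (adjusted p = 0.0591). The gene zma-MIR1432 rose from 2.36 ± 1.25 to 8.66 ± 1.38 FPKM, on 2 to 7 and 15 to 22 reads per library, and lost its call with a pseudocount of 0.1 (adjusted p = 0.0992). Among features known by identifier only, Zm00001d050055 rose from 0.446 ± 0.321 to 29.9 ± 3.99 FPKM and Zm00001d011461 fell from 260 ± 16.8 to 7.36 ± 1.81 FPKM. Of 27109 features tested, 10501 passed the threshold, of which 5337 rose and 5164 fell. The gene zma-MIR408b, whose mean lay below the level set for naming and which was chosen after its values were seen, fell from 7.17 ± 1.32 to 0.567 ± 0.496 FPKM (log2 fold change -2.43, SE 0.3, limma adjusted p = 4.82e-05), on 20 to 29 and 0 to 3 reads per library. By at least 2-fold, 438 rose and 384 fell, against 741 and 664 with a pseudocount of 0.1 and 800 and 709 with voom. The 3 libraries of each treatment did not overlap for 52.5% of the features, against 10% by chance.

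In ST roots, zma-MIR168a fell from 120 ± 21.9 to 83.4 ± 7.85 FPKM (log2 fold change -0.51, SE 0.11, limma adjusted p = 0.00189, n = 3 each). The gene zma-MIR156d, of the family that targets SPL transcription factor transcripts, fell from 10.1 ± 2.39 to 4.25 ± 0.457 FPKM (log2 fold change -1.06, SE 0.2, limma adjusted p = 0.000861). The gene zma-MIR169n, of the family that targets NF-YA transcripts, rose from 2.9 ± 1.23 to 9.23 ± 4 FPKM, a call lost with a pseudocount of 0.1 (adjusted p = 0.179). Zm00001d037894 rose from 0.33 ± 0.183 to 90 ± 9.69 FPKM and Zm00001d008223 from 0.85 ± 0.308 to 68.6 ± 7.44 FPKM. Zm00001d011461, which had fallen in SS roots, fell from 63.1 ± 9.44 to 2.47 ± 0.849 FPKM, and Zm00001d027700 fell from 129 ± 0.798 to 6.63 ± 0.657 FPKM. In all, 7087 of 27109 features rose and 5332 fell, 616 and 628 of them by at least 2-fold, against 1101 and 1028 with a pseudocount of 0.1 and 1212 and 1110 with voom. The share of called features that rose was 57.1% as deposited and 52% after median-of-ratios scaling, so the excess of rises depended on scaling. Groups did not overlap for 50.8% of the features, against 10% by chance.

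In SS shoots, salinity lowered zma-MIR408b and zma-MIR528a, genes of families whose miRNAs target transcripts of copper proteins. The level of zma-MIR408b fell from 103 ± 6.25 to 45.8 ± 9.7 FPKM (log2 fold change -1.17, SE 0.22, limma adjusted p = 0.000455, n = 3 each), on 381 to 399 and 154 to 213 reads per library. That of zma-MIR528a fell from 32.4 ± 8.01 to 12.6 ± 3.79 FPKM (log2 fold change -1.3, SE 0.26, limma adjusted p = 0.000844). The level of zma-MIR168a rose from 324 ± 21.9 to 409 ± 36.2 FPKM (limma adjusted p = 0.000895). The gene zma-MIR156d stood at 16.3 ± 0.972 and 22.8 ± 4.26 FPKM, a call (limma adjusted p = 0.0193) that median-of-ratios scaling ended (adjusted p = 0.0531). Zm00001d037894 rose from 21.3 ± 1.5 to 524 ± 4.64 FPKM and Zm00001d050055 from 2.12 ± 1.06 to 71.8 ± 3.87 FPKM, whereas Zm00001d048192 fell from 55.7 ± 1.56 to 0.498 ± 0.218 FPKM. Of 24810 features tested, 8327 rose and 5705 fell, 660 and 699 of them by at least 2-fold, against 1047 and 1245 with a pseudocount of 0.1 and 1127 and 1377 with voom. The share of called features that rose was 59.3% as deposited and 47.4% after median-of-ratios scaling, so the balance of directions depends on scaling. Groups did not overlap for 60.9% of the features, against 10% by chance.

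In ST shoots, the called miRNA genes named here rose. The level of zma-MIR168a rose from 55.6 ± 2.79 to 113 ± 6.53 FPKM (log2 fold change 1.01, SE 0.07, limma adjusted p = 6.26e-08, n = 3 each). That of zma-MIR168b rose from 49.6 ± 2.09 to 91.8 ± 2.03 FPKM (limma adjusted p = 0.00118), and that of zma-MIR156d from 10.3 ± 2.1 to 24.2 ± 3.65 FPKM (log2 fold change 1.17, SE 0.15, limma adjusted p = 2.31e-05). Zm00001d044078 rose from 2.33 ± 0.62 to 59.9 ± 0.383 FPKM, and Zm00001d028651 fell from 84.8 ± 4.69 to 5.27 ± 0.725 FPKM. In all, 4697 of 24810 features rose and 5654 fell, 347 and 541 of them by at least 2-fold, against 639 and 1133 with a pseudocount of 0.1 and 714 and 1233 with voom. The share of called features that rose was 45.4% as deposited and 51.8% after median-of-ratios scaling, so which direction held the majority depended on scaling. Groups did not overlap for 51.2% of the features, against 10% by chance.

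**Figure D2:**
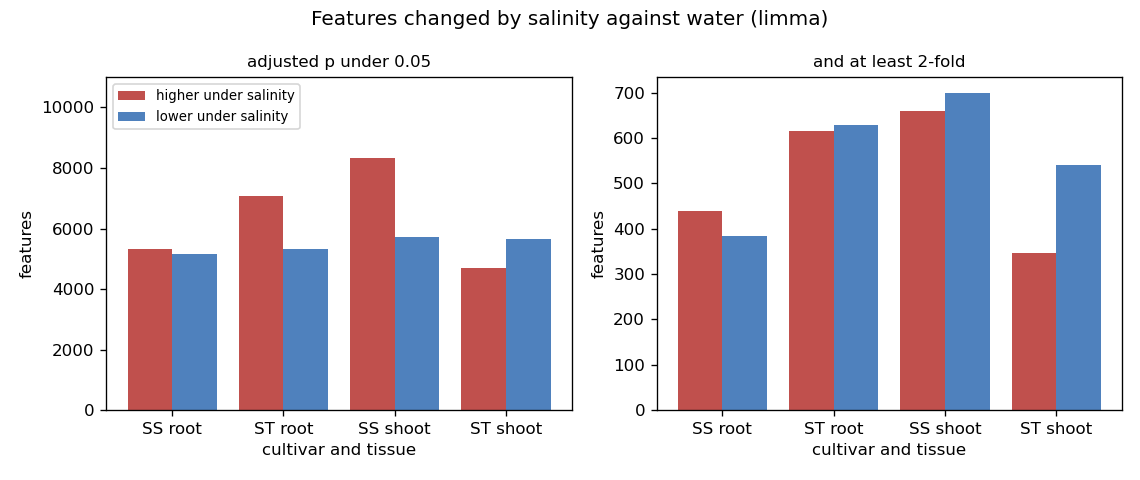
Number of features (y axis) higher or lower under salinity than under water in each cultivar and tissue (x axis), from limma at an adjusted p of 0.05 (left) and with a change of at least 2-fold as well (right). The bars of at least 2-fold changes run from 347 to 699 features.

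The salt response of zma-MIR168a differed between the tissues in both cultivars, falling in roots and rising in shoots. The shoot response exceeded the root response by 0.72 on the log2 scale in SS (SE 0.14, limma adjusted p = 0.000266) and by 1.53 in ST (SE 0.14, limma adjusted p = 1.31e-08), a contrast added after the data were seen. For zma-MIR156d the difference was 2.23 in ST (SE 0.27, limma adjusted p = 8.52e-07) and 0.59 in SS (limma adjusted p = 0.087), where it did not pass.

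The cultivars shared part of their salt response. In roots, 5779 features were called in both, and 61.3% of them changed in the same direction. Both cultivars rose for 2115 features against 1395 expected of independent lists, and both fell for 1425 against 1016. Among features changed by at least 2-fold in both, 138 rose in both against 10 expected, and 83 fell in both against 9. Opposite changes were fewer, with 28 that rose in SS and fell in ST against 10 expected and 7 the other way against 9. In shoots, 6634 features were called in both, 62.1% in the same direction. At 2-fold or more, 115 rose in both against 9 expected, and 96 fell in both against 15, while 23 rose in SS and fell in ST against 14 expected and 18 went the other way against 10. With voom, 474 and 603 such features went the same way in roots and shoots and 109 and 135 opposite ways; with a pseudocount of 0.1, 433 and 529 went the same way and 94 and 121 opposite ways. These comparisons share no libraries. Fold changes correlated across features with Pearson coefficients of 0.25 in roots and 0.24 in shoots, and features are not independent replicates.

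**Figure D3:**
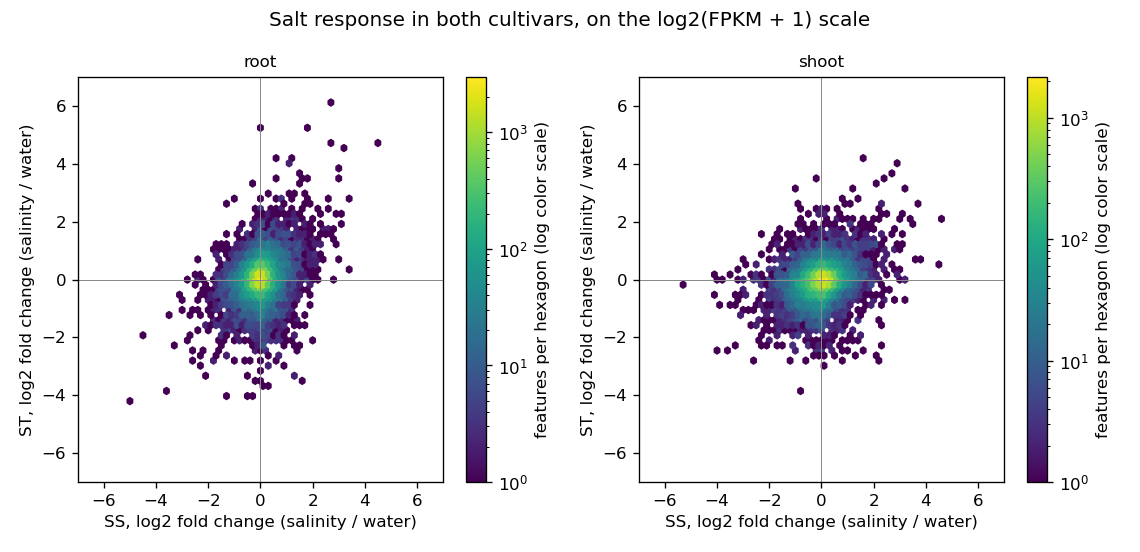
Log2 fold change of salinity over water in SS (x axis) and ST (y axis) for each tested feature of roots (left, 27109 features) and shoots (right, 24810), with the number of features per hexagon as color. The clouds lean along the diagonal, with Pearson coefficients across features of 0.25 and 0.24, and reach into all 4 quadrants.

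The difference between the cultivars' responses was tested as the interaction of cultivar and treatment. In roots, zma-MIR156k and zma-MIR156d responded lower in ST than in SS, by -1.19 (SE 0.28, limma adjusted p = 0.00463) and -0.92 (SE 0.28, limma adjusted p = 0.0208) on the log2 scale. The latter call was lost with voom on recovered reads (adjusted p = 0.123) and without SS salinity replicate 1 (adjusted p = 0.052). The response of zma-MIR408b was 2.6 higher in ST (SE 0.43, limma adjusted p = 0.000428), where its level stood at 0.42 ± 0.384 and 0.631 ± 0.548 FPKM on 0 to 3 reads per library, so that a fall in ST roots was not detectable at this depth. Zm00001d008223 rose in ST roots and stood at 0.0888 ± 0.116 and 0.0592 ± 0.0213 FPKM in SS. Zm00001d000163 rose from 10.8 ± 0.504 to 32.8 ± 0.962 FPKM in SS roots and fell from 82.8 ± 3.83 to 6.26 ± 0.104 FPKM in ST roots. Of 27109 features, 11318 differed in response, 785 with a higher and 882 with a lower response in ST by at least 2-fold. Of these 1667, 748 (44.9%) were called in opposite directions in the cultivars, against 970 of 2683 (36.2%) with voom and 926 of 2645 (35%) with a pseudocount of 0.1.

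In shoots, zma-MIR408b and zma-MIR528a separated the cultivars. The response of zma-MIR408b was 2.12 higher in ST on the log2 scale (SE 0.31, limma adjusted p = 8.17e-05), where its level went from 1.05 ± 0.765 to 2.78 ± 0.294 FPKM on 1 to 7 and 9 to 10 reads per library. That of zma-MIR528a was 2 higher (SE 0.37, limma adjusted p = 0.000574), from 3.85 ± 1.84 to 6.69 ± 1.9 FPKM in ST. Within ST shoots both were called as rising, zma-MIR408b by 0.95 (SE 0.22, limma adjusted p = 0.00317) and zma-MIR528a by 0.7 (SE 0.26, limma adjusted p = 0.0471). Both ST calls lay outside the rule for naming, by mean level for zma-MIR408b and by overlapping groups for zma-MIR528a. The rise of zma-MIR168a was also larger in ST, by 0.68 (SE 0.09, limma adjusted p = 5.81e-05). Zm00001d039524 rose from 5.79 ± 0.288 to 30 ± 5.25 FPKM in SS shoots and fell from 45.3 ± 0.639 to 5.55 ± 0.606 FPKM in ST shoots. Of 24810 features, 12739 differed in response. The response was higher in ST for 38.9% of them as deposited and for 52.6% after median-of-ratios scaling, which shifted the log2 differences of single features by a median of 0.11. At 2-fold or more, 826 were higher and 951 lower in ST as deposited, against 1036 and 771 after scaling. Of the 1777, 769 (43.3%) were called in opposite directions, against 1027 of 2858 (35.9%) with voom and 994 of 2873 (34.6%) with a pseudocount of 0.1.

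**Figure D4:**
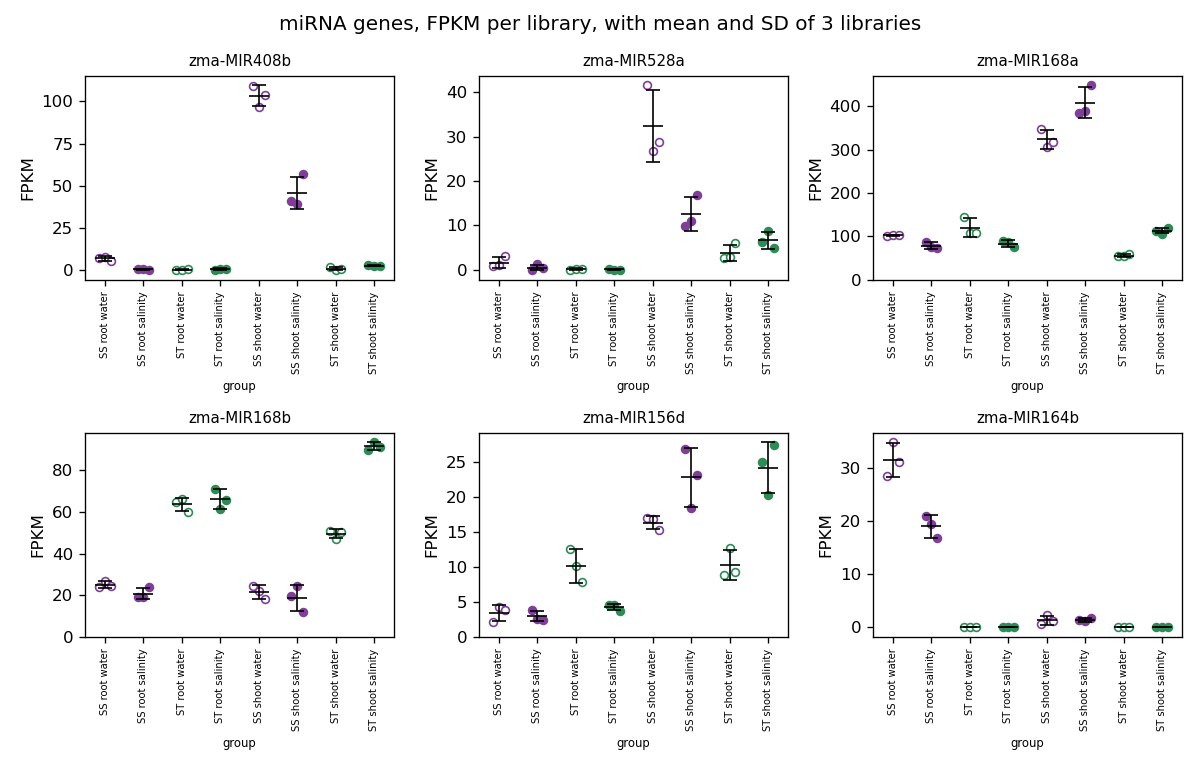
FPKM (y axis) of 6 miRNA genes in each library of the 8 groups (x axis); open circles are water, filled circles salinity, bars the mean and SD of 3 libraries. The gene zma-MIR408b stood at 103 ± 6.25 FPKM in SS shoots under water and at 1.05 ± 0.765 FPKM in ST shoots, and zma-MIR164b had 0 reads in all 12 ST libraries.

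Between the cultivars under water, zma-MIR164b stood at 31.5 ± 3.23 FPKM in SS roots and had 0 reads in ST roots. Against a floor of 3 reads over the 3 ST libraries (0.298 FPKM), it was at least 106-fold lower in ST, and at least 56.3-fold lower under salinity. In shoots, zma-MIR408b was lower in ST than in SS by 5.74 on the log2 scale under water (log2 fold change -5.74, SE 0.22, limma adjusted p = 2.03e-11) and zma-MIR168a stood at 324 ± 21.9 in SS and 55.6 ± 2.79 FPKM in ST. The gene zma-MIR168b was higher in ST in both tissues and treatments, at 63.8 ± 3.12 against 25 ± 1.67 FPKM in roots and 49.6 ± 2.09 against 21.5 ± 3.15 FPKM in shoots under water. Zm00001d050635 stood at 1820 ± 117 FPKM in ST roots and 0.368 ± 0.104 in SS roots, and Zm00001d035684 at 0.526 ± 0.451 in ST roots and 1930 ± 43.3 in SS roots. Under water, 19174 of 27109 features differed in roots and 19865 of 24810 in shoots, 5763 and 6905 of them by at least 2-fold, or 3659 and 4485 where an FPKM of at least 5 in 3 libraries was required. Under salinity, 19873 differed in roots and 19868 in shoots. In shoots under salinity, 36.2% of the called features were higher in ST as deposited and 49.8% after median-of-ratios scaling, which shifted the log2 fold changes by a median of 0.2. At 2-fold or more, 2708 were higher and 4136 lower in ST as deposited, against 3287 and 3361 after scaling.

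Between the tissues under water, zma-MIR408b and zma-MIR528a were higher in shoots than in roots of SS, at 103 ± 6.25 against 7.17 ± 1.32 FPKM and 32.4 ± 8.01 against 1.64 ± 1.24 FPKM (limma adjusted p = 8.97e-11 and 3.27e-10, n = 3 each). The gene zma-MIR164b was lower in SS shoots, at 1.4 ± 0.853 against 31.5 ± 3.23 FPKM. In ST, zma-MIR168a was lower in shoots, at 55.6 ± 2.79 against 120 ± 21.9 FPKM. Zm00001d023343 stood at 4470 ± 161 FPKM in SS shoots and 1.98 ± 0.52 in SS roots, and Zm00001d037513 at 2080 ± 43.8 in ST shoots and 0.241 ± 0.0713 in ST roots. Of 29127 features, 23940 differed in SS and 24786 in ST. As deposited, 30.3% and 25.3% of these were higher in shoots, and after median-of-ratios scaling 47.3% and 47.6%. That scaling shifted the log2 fold changes by a median of 0.41 in SS and 0.56 in ST, and gave 1265 and 2487 of the called features a call in the opposite direction.

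Tests by class of identifier were added after the data were seen, with camera over 3 classes in the 4 salinity contrasts and the 2 interactions. The added transcript models ranked lower than other features in SS shoots, with 208 rising, 427 falling and 1159 not called. This passed with a preset correlation of 0.01 (camera adjusted p = 0.00576) and not with an estimated one (adjusted p = 0.457). No other class passed in any of the 6 contrasts. Of the 15 miRNA genes tested in roots, 2 rose and 6 fell in SS and 1 rose and 5 fell in ST. Of the 20 tested in shoots, 4 rose and 3 fell in SS and 5 rose and 1 fell in ST.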

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

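The tests of library scaling, swapped labels, read depth and added transcript models, the counts of other splits and the tissue contrast were chosen after the results were seen. The tests of short features, few reads and copper-linked genes had their predictions written first.

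The results listed here stood out because the salt response differed between the cultivars or tissues by an interaction test. In roots 11318 features differed and in shoots 12739. In roots the log2 differences, ST minus SS, were 0.69 for zma-MIR164b, which has 0 reads in ST and lost its call with voom (adjusted p = 0.276), and 0.32 for zma-MIR168b, a call lost in 19 of 23 refits (adjusted p of 0.00533 to 0.249). They were -1.19 for zma-MIR156k, -0.92 for zma-MIR156d, 2.6 for zma-MIR408b, with 0 to 3 reads per library in ST, 5.28 for Zm00001d008223, with 0 to 4 reads per library in SS, 3.96 for Zm00001d019400, -5.05 for Zm00001d000163 and -4.62 for Zm00001d054060. In shoots they were 2.12 for zma-MIR408b, 2 for zma-MIR528a, 1.11 for zma-MIR168b, 0.72 for zma-MIR156d, 0.68 for zma-MIR168a, 5.15 for Zm00001d048192, with 0 to 3 reads per library in ST, 4.19 for Zm00001d031303, -5 for Zm00001d039524 and -4.66 for Zm00001d021816. Between tissues, shoot minus root, the differences were 0.72 in SS and 1.53 in ST for zma-MIR168a and 2.23 in ST for zma-MIR156d. Groups of 3 libraries were not searched for outlying libraries; refits without each library stand with the processing alternatives.

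The first pattern is the set of features with an interaction of at least 2-fold and opposite salt responses in the cultivars, 748 in roots and 769 in shoots. Selection on the interaction favors opposite calls. Of all features called in both root responses, 1178 rose in SS and fell in ST against 1050 expected of independent lists. The other way went 1061 against 1350. In shoots the counts were 1453 against 1898 and 1061 against 1080. At 2-fold or more in both cultivars, 35 and 41 were opposite. Library scaling is argued against only as far as median-of-ratios rescaling estimates it. That rescaling shifted the log2 differences between the responses by medians of -0.02 in roots and 0.11 in shoots. It left 734 and 803 features with such an interaction and opposite calls. Swapped treatment labels in 1 cultivar are argued against by the features changed by at least 2-fold in both, of which 86.3% in roots and 83.7% in shoots went the same way. A difference in stage or harvest time between the cultivars was not tested, because the labels give no time, and it stays open beside a difference in cultivar.

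The second pattern is the set of features with reads in 1 cultivar only and a group mean of at least 1 FPKM, 474 in SS and 759 in ST. Depth is argued against: by the same rule, a split of the 24 libraries by treatment, at similar depth, gave 5 features with reads only under water and 2 only under salinity. Transcript models added to the reference set are over-represented, but 51.3% and 46.9% of the features were Zm00001d models, so these additions are not the whole source. Sequence or presence differences between each cultivar and the reference may account for the pattern and were not tested, since no genome was used here.

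The third pattern is the fall of zma-MIR408b and zma-MIR528a in SS shoots, with a response that was higher in ST shoots. In roots too, zma-MIR408b fell in SS (log2 fold change -2.43) while ST, at 0 to 3 reads per library in both treatments, left no room for a fall, so the difference of 2.6 restates the fall in SS; the gene was chosen there after its values were seen. For a bias against short features, the 550 other tested features of at most 270 bases had a median log2 change of 0 (quartiles -0.35 and 0.38). Of these, 4.55% fell as far as zma-MIR408b. Features near 0 FPKM in SS shoots cannot fall that far on this scale, and features of similar level were not compared. Short features as a set therefore did not fall, but a bias among well-expressed short features is not excluded. For few reads in ST shoots, voom, which weights reads by precision, kept both differences between the cultivars (adjusted p = 0.000489 and 0.000642). A well-measured fall in SS can give such a difference however few reads ST has. Few reads in ST shoots, 1 to 7 per library for zma-MIR408b under water, are therefore not excluded by that difference. Within ST shoots both genes were called as rising, also on few reads. Over the groups under water and salinity, zma-MIR408b had 12 and 28 reads (limma adjusted p = 0.00317) and zma-MIR528a had 36 and 57 (limma adjusted p = 0.0471). A shared response of copper-linked miRNA genes may be a biological source, but it cannot be told apart here, because the other 4 genes of the MIR397, MIR398 and MIR408 families had 0 reads in the 6 SS shoot libraries, and zma-MIR528b, at -0.2 (SE 0.21, limma adjusted p = 0.445), had 1 read.

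Other splits of the libraries were counted for each number of called features. With 3 libraries against 3 there are only 10 splits, too few for a share under 0.05, and 1 of the 10, the real split, reached the real count in every such comparison. The real and highest other counts for salinity were 10501 and 1 in SS roots, 12419 and 3 in ST roots, 14032 and 3 in SS shoots, and 10351 and 2 in ST shoots. Between cultivars they were 19174 and 0 in roots and 19865 and 0 in shoots under water, and 19873 and 0 in roots and 19868 and 0 in shoots under salinity. Between tissues they were 23940 and 3 in SS and 24786 and 4 in ST. For the interactions 100 splits within cultivars were drawn. In shoots 1 of 100, the real one, reached 12739. The highest other gave 6871, with all SS labels exchanged and 4 ST labels kept. In roots 2 of 100 reached 11318. The other gave 12465 and kept all 6 ST labels while exchanging all SS labels. It measured the sum of the responses, a structure of the samples rather than noise. Most other splits mix salinity and water libraries within a group, so the salt effect itself widens the spread and lowers their counts. Not all splits were drawn. These counts therefore cannot decide whether the interactions arose by chance.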

How the results depend on the processing

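Voom on recovered reads, the counts at 2-fold or more under other settings and the refits of zma-MIR408b in roots were chosen after the data were seen, and the other alternatives before. Of the total counts at the threshold, only those with a floor of 2-fold moved by over 1.5 times, by its construction. It left 822 features in SS roots, 1244 in ST roots, 1359 in SS shoots and 888 in ST shoots for salinity, and 1667 and 1777 for the root and shoot interactions. Between cultivars it left 5763 and 5995 in roots and 6905 and 6844 in shoots (water, salinity), between tissues 11781 in SS and 12443 in ST, and 221 and 211 features changed alike in both cultivars in roots and shoots. Counts at 2-fold or more for salinity and interactions rose by over 1.5 times with a pseudocount of 0.1 (1405, 2129, 2292, 1772, 2645 and 2873, in the order above) and with voom (1509, 2322, 2504, 1947, 2683 and 2858), and those between cultivars fell to 3659 and 3804 in roots and 4485 in shoots under water with the filter of FPKM 5. The features higher in shoots went from 7247 to 10901 in SS and from 6271 to 10926 in ST with median-of-ratios rescaling. All other settings, leaving out a library aside, gave 7182 to 11465 features in SS roots, 9103 to 13330 in ST roots, 11076 to 14731 in SS shoots and 7690 to 10796 in ST shoots. Leaving out 1 library gave 8635 to 9053, 10913 to 11888, 12715 to 12998 and 9028 to 9478 there, 10072 to 11238 and 11768 to 12237 for the root and shoot interactions, 17990 to 18436 and 18615 to 19327 for the cultivars in roots (water, salinity), 18897 to 19177 and 19123 to 19306 in shoots, and 23378 to 23519 and 24282 to 24363 for the tissues in SS and ST. Replicate numbers paired the libraries weakly at most: deviations of same-numbered libraries correlated at -0.102 to 0.131, over 0.1 in 2 of 36 pairs. Both of these were root pairs with ST water replicate 1. Of 12 root and 12 shoot libraries, 7 and 5 matched best with their own number. The number of such matches by chance was not computed, so a weak pairing in roots is not excluded. A replicate block gave 10390, 12312, 13781 and 10105 features for salinity in SS roots, ST roots, SS shoots and ST shoots, and 11120 and 12462 for the interactions. Of 100 named features and comparisons, zma-MIR168b between ST tissues reversed with median-of-ratios rescaling (0.31 against -0.36, adjusted p = 0.0749). That rescaling shifted the log2 fold changes of this contrast by a median of 0.56, and zma-MIR168b moved in the same direction. Which scaling is right was not tested. Across 1864 refits of named features 84 calls were lost, 30 of them, in 10 results, by leaving out 1 library. The gene list tests and the fixed panel could not be run, since the lists had 0 members. The fall of zma-MIR408b in SS roots, on 0 to 3 reads under salinity, was not tested when any of its 3 water libraries was left out, since the filter then removed it. Depth limits several miRNA genes, with 0 to 3 reads per library in some groups.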

Other observations

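The tests by identifier number were chosen after the result was seen. Predictions for the covariances were written first.

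Reads in 1 cultivar only reached high levels for some features. Zm00001d039648 stood at 114 ± 0.84 FPKM in SS roots under water, with 0 reads in the 12 ST libraries, at least 1072-fold above a floor of 3 reads over the 3 ST root libraries under water (0.106 FPKM). Zm00001d009803 stood at 91.8 ± 6.33 FPKM in ST roots under water, with 0 reads in the 12 SS libraries, at least 1266-fold above the same kind of floor in SS roots under water (0.0724 FPKM). At a group mean of at least 10 FPKM, 55 features had reads only in SS and 87 only in ST. Both features were chosen after their values were seen.

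One hypothesis was that salinity moves each cultivar towards the level of the other. The covariance over features of the salt response with the other cultivar's difference under water was 0.0418 in SS roots, 0.0613 in SS shoots, 0.0982 in ST roots and 0.127 in ST shoots. Shared water libraries alone gave 0.00529 to 0.00665, 0.00468 to 0.0056, 0.00533 to 0.00665 and 0.00472 to 0.00555 in simulations (central 95% range), so all 4 lay above. The relation was weak, with Pearson coefficients across features of 0.1, 0.1, 0.19 and 0.25 in the same order. The medians went with the hypothesis in ST and only in part in SS. Features that fell by at least 2-fold in SS stood 0.74 (roots) and 0.96 (shoots) lower in ST under water on the log2 scale, medians of -0.74 and -0.96, but those that rose did not stand higher in ST, with medians of -0.16 and -0.26. Features that rose in ST stood higher in SS under water, with medians of 0.46 (roots) and 1.16 (shoots), and those that fell stood lower, with medians of -0.89 and -1.17. A floor may contribute, since a feature absent in a cultivar cannot fall there, and was not separated from the hypothesis.

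A second hypothesis was that changed features lie together by identifier number. Over windows of 50 consecutive tested Zm00001d features, the percentage that differed between the cultivars under water by at least 2-fold had an SD of 7.01 in roots and 7.68 in shoots, against medians of 5.47 and 6.11 for shuffled identifiers (permutation p = 1e-04 each, the smallest possible here, adjusted p = 3e-04 over 6 tests). For salinity the SDs were 2.64 in SS roots, 3.17 in ST roots, 3.51 in SS shoots and 2.76 in ST shoots, against 2.42, 2.96, 3.25 and 2.55 for shuffled identifiers (adjusted permutation p = 0.0052, 0.0144, 0.0124 and 0.0124). The excess was small in each, and related neighbouring genes, which may share reads, could give it.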
